A study of Mus musculus with 2 samples.

How the data were processed

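RNA was measured in the cerebellum of adult male mice aged 8 weeks, of a C57BL/6N substrain (B6NCrl in the labels), by sequencing of polyadenylated RNA. Per the labels, RNA longer than a stated size limit was taken and spike-in RNA was used. There was 1 group of 2 samples, called replicate 1 and replicate 2 after the replicate numbers in the labels. The labels describe each sample as coming from an individual mouse, and also give both the same donor identifier, so their independence rests on the description alone. With no contrasting group, no test between conditions was possible and no p-value is given; the spread is that between these samples.

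The authors deposited a gene table and a transcript table for each sample, quantified against build mm10 and annotation release M4, per the notes deposited with the files. The column names and layout are those of RSEM, and the aligner, the quantifier's version and its settings are not given in the sources used here. The deposited expected counts are estimates of the reads per gene or transcript in which reads that match several places were split by a model, so they need not be whole. The deposited TPM values are counts divided by effective length and scaled to a fixed sum over every row, with spike-ins and tRNAs included. The deposited FPKM values are counts divided by effective length and by the number of assigned reads. The deposited percent values give each transcript's share of its gene. The deposited tables also hold posterior means and posterior standard deviations of the counts, which measure how ambiguous the assignment of reads was within a library.

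Each gene table had 69691 rows, of which 43346 were Ensembl genes, 26248 were tRNA rows with numeric identifiers, 96 were ERCC spike-ins and 1 was phiX. In 69658 rows the length exceeded the effective length by 35 nt, the difference given by a fixed fragment of 36 nt. Reads of that length resolve isoforms and close gene copies poorly. Names, biotypes, GC content and positions were taken from GENCODE M21 on GRCm38, the same assembly as mm10, by matching identifiers without their version; 42462 genes and 101510 of 103639 Ensembl transcripts matched. Gene models of the 2 releases differ, so positions are those of M21.

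The total expected counts were 13110910 in replicate 1 and 13966716 in replicate 2, so that 3 counts, the limit that a count of 0 allows, were 2.29e-05% and 2.15e-05% of a library. Intervals on counts are exact (Clopper-Pearson) 95% intervals, and they cover counting error only. TPM divides by the sum over all rows. Nuclear protein-coding genes held 41.6% of TPM in replicate 1 and 49.6% in replicate 2, while rows shorter than 200 nt held 21.4% and 16.2% of TPM from 0.908% and 0.584% of the counts. As a result, the median protein-coding gene was 1.22-fold higher in replicate 2 on the TPM scale. Levels are therefore given in TPM, and differences between the mice on counts scaled by the TMM method. The SD of a level or list median in TPM holds this shift of the scale as well as the spread between the mice.

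A gene was called detected at 1 TPM or more in both mice. Family composition is each member's share of the family's TPM. Transcript shares were computed for genes with 2 or more annotated transcripts and at least 5 TPM in both mice. Expected counts were rounded, and the TMM factors and the dispersion of an intercept-only model over genes with at least 10 counts in both mice were estimated with edgeR 4.0.16 in R 4.3.3; DESeq2 1.42.0 gave the alternative size factors. The log2 ratio of replicate 2 over replicate 1 was computed from scaled counts with a prior count of 0.5. Genes with a mean count of at least 50 that differed by 2-fold or more are reported. Such a difference compares 2 libraries and has no replicate check. Of 54 gene lists, those with 3 or more members at a mean count of at least 20 were tested. The median log2 ratio of a list was placed among the medians of 10000 random lists of the same size, matched on mean count in 20 bins, and called outside when it left the central 95%. Genes of 1 cell type vary together, so these percentiles describe the libraries and are not p-values. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

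On simulated counts with the means and sizes of these libraries, a coefficient of variation of 10% was recovered as 9.95% and 20% as 20.1%, over 15613 genes. At 10%, the 2-fold rule found 98% of the genes changed by 1.5 on the log2 scale and 100% of those changed by 3, and called 0.0496% of unchanged genes; at 20% these were 93%, 100% and 2.41%. Random lists of 12 genes left the central range in 3% of 200 draws, and did so in 18.5%, 61% and 98.5% after adding 0.1, 0.2 and 0.4 to their log2 ratios, on 14482 genes.

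The groups, the lists, the thresholds and the alternatives were chosen before the data were examined, except where stated; the further gene lists and tests in the closing part were written later. Genes named in the text are the 25 nuclear protein-coding genes with the highest mean TPM, the 6 detected members of each list with the highest TPM and its members under 1 TPM, every member of lists of 8 or fewer, family members holding at least 1% of their family, the 15 largest differences per direction, list members that differed by 2-fold or more, and, for transcripts, a fixed list of 30 genes and the 10 highest genes with differing largest transcripts. Alternatives were other units, scalings, pseudocounts, count minimums, list statistics, removal of a linear trend on GC content and length, and each mouse left out in turn. The tRNA, spike-in and phiX rows were left out of the comparisons.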

Results

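Polyadenylated RNA was sequenced from the cerebellum of 2 adult male mice, and the deposited tables gave an estimated level for each gene and transcript. The libraries held 13110910 and 13966716 expected counts. Mitochondrially encoded genes took 12.7% of the counts in replicate 1 and 10.9% in replicate 2. Nuclear protein-coding genes took 67.3% and 73.3%. A single long non-coding gene, Gm42418, took 8.73% and 6.55%, and a gene without a name in the annotation used took 5.97% and 3.80%. The labels name no contrast, so the data address which genes the tissue expresses and how far the mice differed.

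In both mice 15236 of 43346 genes were detected, among them 12502 of 21474 protein-coding genes (58.2%) and 267 of 2777 lincRNA genes (9.61%). Most lay at low or middling levels: 6666 had a mean of 1 to 10 TPM, 7591 of 10 to 100 TPM, 921 of 100 to 1000 TPM and 58 of 1000 TPM or more. Replicate 1 alone gave 16202 genes and replicate 2 alone 16774.

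Snap25, Mbp, Plp1 and the calmodulin genes were among the 25 nuclear protein-coding genes with the highest mean TPM, a ranking that leaves out mitochondrially encoded genes. Snap25 (ENSMUSG00000027273), which encodes a membrane protein of synaptic vesicle fusion and lies on chromosome 2 of GRCm38 (136713453 to 136782428), stood at 2013 ± 310 TPM (SD, n = 2, as for all levels that follow). Mbp, the myelin basic protein gene, stood at 1921 ± 25.3 TPM and Plp1, which encodes the main proteolipid of myelin, at 982 ± 48.5 TPM. These SDs include the 1.22-fold shift of the TPM scale, so a small SD does not mean a small difference between the mice. On scaled counts the log2 ratio was 0.04 for Snap25 and -0.20 for Mbp. The calmodulin genes Calm2, Calm3 and Calm1 stood at 1917 ± 20.6, 1222 ± 88.6 and 1006 ± 30.7 TPM. Aldoc, a glycolytic aldolase that also marks a class of Purkinje cells, stood at 1270 ± 196 TPM, and Pcp4, a calmodulin regulator abundant in Purkinje cells, at 1108 ± 181 TPM. Lars2, a mitochondrial leucyl-tRNA synthetase gene, led the ranking of nuclear protein-coding genes at 3786 ± 971 TPM, with 4473 TPM in replicate 1 and 3100 TPM in replicate 2, followed by Cdr1 at 2669 ± 33.2 TPM. On scaled counts Lars2 was lower in replicate 2, with a log2 ratio of -0.80, as was the non-coding Gm42418, with -0.53. Whether the reads assigned to Lars2 and Gm42418 came from the transcripts of these genes was not tested. Among the 25 highest genes were also Fth1, Mt1, Eef1a1, Atp1b1, Hspa8, Ndufa4, Tuba1a, Ywhah, Atp1b2, Ddx5, Atp5b, Ptgds, Cox8a, Nptn and Hsp90aa1, between 1426 ± 16.3 TPM for Fth1 and 783 ± 143 TPM for Hsp90aa1. When counts were not divided by length, only 11 of the 25 remained among the highest.

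By list median, markers of granule cells, Purkinje cells, Bergmann glia, astrocytes and oligodendrocytes stood above those of other brain regions. Each list median is that of the members' mean TPM, and the SD beside it is that of the medians of the 2 mice. All 14 granule cell markers were detected, with a median of 205 ± 59.7 TPM, and all 19 Purkinje cell markers, with a median of 167 ± 9.77 TPM. Among granule cell markers, Cbln3 stood at 625 ± 33.0 TPM, Cbln1 at 565 ± 98.2 TPM, Gabra6 at 455 ± 57.3 TPM and Zic1 at 356 ± 60.5 TPM. Among Purkinje cell markers, Pcp2 stood at 634 ± 28.2 TPM, Pvalb at 574 ± 2.59 TPM, Rgs8 at 450 ± 31.2 TPM and Car8 at 444 ± 11.1 TPM. The granule cell median exceeded the Purkinje cell median by 0.22 ± 0.35 on the log2 scale, less than the spread between the mice: the difference was -0.03 in replicate 1 and 0.47 in replicate 2.

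Glial lists followed at lower medians. Bergmann glia, the radial astrocytes of the cerebellar cortex, had a median of 129 ± 14.2 TPM over 10 of 10 detected markers, with Slc1a3 at 467 ± 0.969 TPM. Oligodendrocyte markers, with 12 of 12 detected, had a median of 91.2 ± 19.5 TPM, and astrocyte markers, with 10 of 10, one of 86.9 ± 1.44 TPM. The granule cell median exceeded the oligodendrocyte median by 1.11 ± 0.13 on the log2 scale. Molecular layer interneurons had a median of 20.9 ± 0.509 TPM with 12 of 12 markers detected, and medians of 22.2 TPM in replicate 1 and 21.5 TPM in replicate 2. Cerebellar nuclei had a median of 11.8 ± 4.79 TPM with 6 of 8, Golgi cells 10.8 ± 6.12 TPM with 5 of 6, and unipolar brush cells 10.7 ± 2.74 TPM with 4 of 6. Microglia had a median of 5.08 ± 1.33 TPM over 11 of 11 markers and endothelial cells one of 9.85 ± 1.74 TPM over 10 of 10. Oligodendrocyte precursors stood at 4.47 ± 1.09 TPM, meningeal fibroblasts at 6.28 ± 1.46 TPM and mural cells at 3.26 ± 0.841 TPM. Choroid plexus genes had a median of 3.43 ± 3.66 TPM, with 6.20 TPM in replicate 1 and 1.02 TPM in replicate 2 and 6 of 11 detected, and ependymal genes one of 2.56 ± 1.34 TPM with 5 of 8 detected. Red blood cell genes were present at a median of 55.5 ± 13.4 TPM, with Hbb-bs at 217 ± 68.6 TPM.

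Most listed genes of other regions were not detected. Of 20 telencephalic genes 4 were detected, and the median of the list was 0.12 TPM. The 4 were Penk at 88.7 TPM in replicate 1 and 107 TPM in replicate 2, Ppp1r1b at 70.4 ± 8.03 TPM, Camk2a at 45.5 ± 7.74 TPM and Neurod6 at 3.73 ± 0.0919 TPM. Over all 20 genes the granule cell median was higher by 10.38 ± 0.19 on the log2 scale, and over the 4 detected alone by 1.92. Foxg1, a forebrain transcription factor, had no counts in either mouse. Of 19 Hox genes, which mark hindbrain and spinal cord behind the cerebellum, none reached 1 TPM in both mice. Of 10 brainstem monoaminergic and cholinergic genes 3 were detected (Th, Ddc and Slc18a2), and of 7 pineal and pituitary genes none was. Of 8 white blood cell genes 1 was detected and of 6 skeletal muscle genes 3. The patterning list of the cerebellum and hindbrain had 14 of 20 detected, led by Zic1, Zic2, Pax6 (73.6 ± 13.2 TPM), Zic4 and En2 (34.5 ± 5.78 TPM). Xist, the RNA of the inactive X chromosome, stood at 0.0700 ± 0.0141 TPM, and the Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d stood at 39.6 ± 4.25, 26.5 ± 0.0566, 13.8 ± 0.304 and 12.7 ± 1.90 TPM in these male mice.

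**Figure D1:**
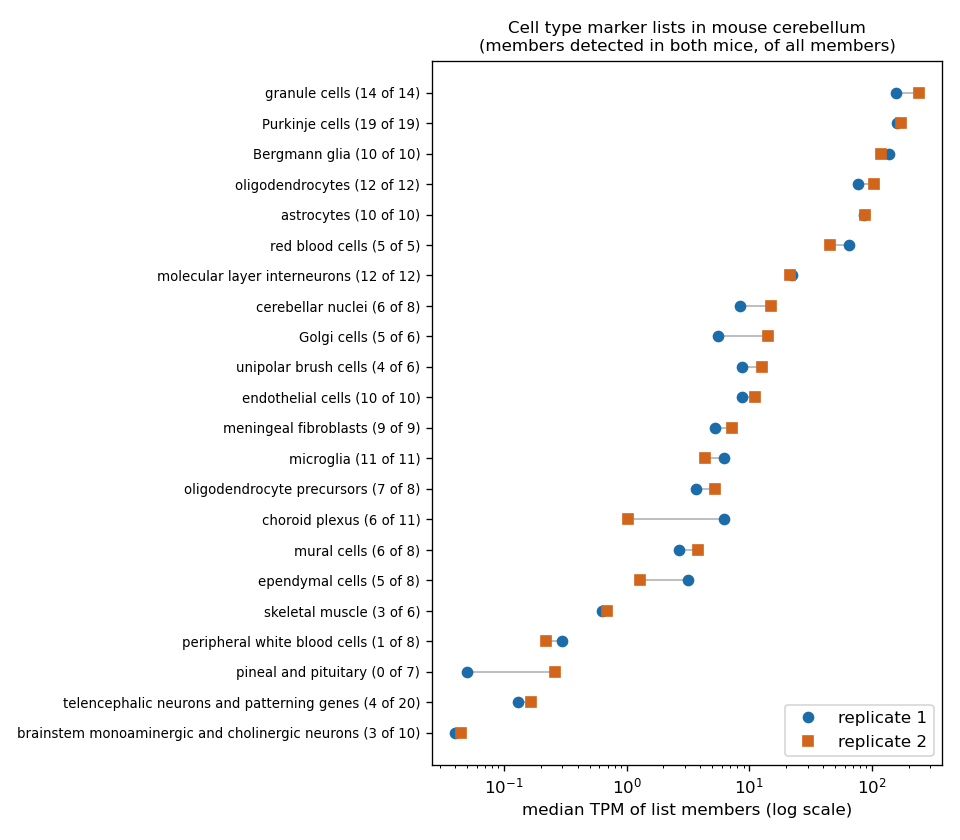
Median TPM (log scale) of 22 cell type marker lists in each mouse, circles for replicate 1 and squares for replicate 2, with the members detected in both mice. Granule and Purkinje cell lists lie near 205 and 167 TPM, and the telencephalic list near 0.12 TPM; the choroid plexus list differs most between the mice.

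Other fixed lists covered states of the tissue and disease genes. Of 30 ataxia genes 28 were detected, at a median of 33.3 ± 2.29 TPM, with Kcnc3 at 332 ± 73.3 TPM, Itpr1 at 301 ± 8.78 TPM, Syne1 at 210 ± 58.0 TPM and Prkcg at 141 ± 37.5 TPM. Of 18 circadian clock genes 18 were detected, led by Tef at 144 ± 7.63 TPM, Nr1d2 at 78.1 ± 2.52 TPM and Nr1d1 at 64.7 ± 14.8 TPM. Of 27 imprinted genes 23 were detected, led by Meg3 at 774 ± 306 TPM and Rian at 587 ± 126 TPM. Proliferation genes were low, with a median of 1.22 ± 0.0460 TPM and Mki67 at 0.115 ± 0.0212 TPM. Interferon response genes had a median of 2.39 ± 0.856 TPM, heat shock genes of 74.5 ± 18.5 TPM and glucocorticoid responsive genes of 16.9 ± 6.29 TPM, and 16 of 20 immediate early genes were detected. The 15 mitochondrially encoded genes had a median of 8620 ± 425 TPM. Among Purkinje cell subclass genes, Aldoc exceeded Plcb4 by 2.62 ± 0.17 on the log2 scale, and Plcb4, of the zebrin-negative class, exceeded Plcb3 by 4.07 ± 0.47. Aldoc is also in the astrocyte list, so in whole tissue its ratio to Plcb4 does not measure the balance of Purkinje cell classes.

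Most receptor, channel and transporter families were dominated by few members, and in 16 of 17 families the leading member was the same in both mice. Gabra6, a GABA-A receptor subunit of granule cells, made up 65.8% ± 2.28 of the alpha subunit transcripts and Gabra1 27.8% ± 2.17. Grin2c held 68.8% ± 6.12 of the NMDA receptor GluN2 transcripts, Grin2a 18.2% ± 5.90 and Grin2b 7.99% ± 0.101. Slc17a7, the vesicular glutamate transporter of granule and mossy fibre terminals, held 79.4% ± 0.0581 of the vesicular transporters, and Slc32a1, that of GABA and glycine, 16.9% ± 1.19. Slc1a3 held 59.5% ± 1.46 of the glutamate transporters, ahead of Slc1a2 with 29.2% ± 2.35 and Slc1a6, a Purkinje cell transporter, with 9.23% ± 3.42.

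Cbln3 held 52.6% ± 3.07 and Cbln1 47.3% ± 2.99 of the cerebellins. Zic1 held 61.6% ± 1.12 of the Zic factors, Cacna1a, the P/Q-type channel gene, 42.4% ± 2.23 of the calcium channel alpha1 subunits, and Scn2a 48.8% ± 0.437 of the sodium channel alpha subunits. Kcnc3 and Kcnc1 held 52.6% ± 0.397 and 44.9% ± 0.0335 of the Kv3 channels, Kcna1 52.3% ± 1.95 of the Kv1 channels and Grm4 53.6% ± 5.14 of the metabotropic glutamate receptors. The AMPA receptor family had no stable leader: Gria4 led in replicate 1 with 34.4% and Gria2 in replicate 2 with 30.6%, and the mean shares of Gria4, Gria1 and Gria2 were 32.4% ± 2.84, 30.9% ± 4.41 and 25.8% ± 6.78. The rank order of all members was the same in 11 of 17 families. By count, without division by length, the share of Gabra6 was 49.0% and that of Grin2c 60.2%.

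**Figure D2:**
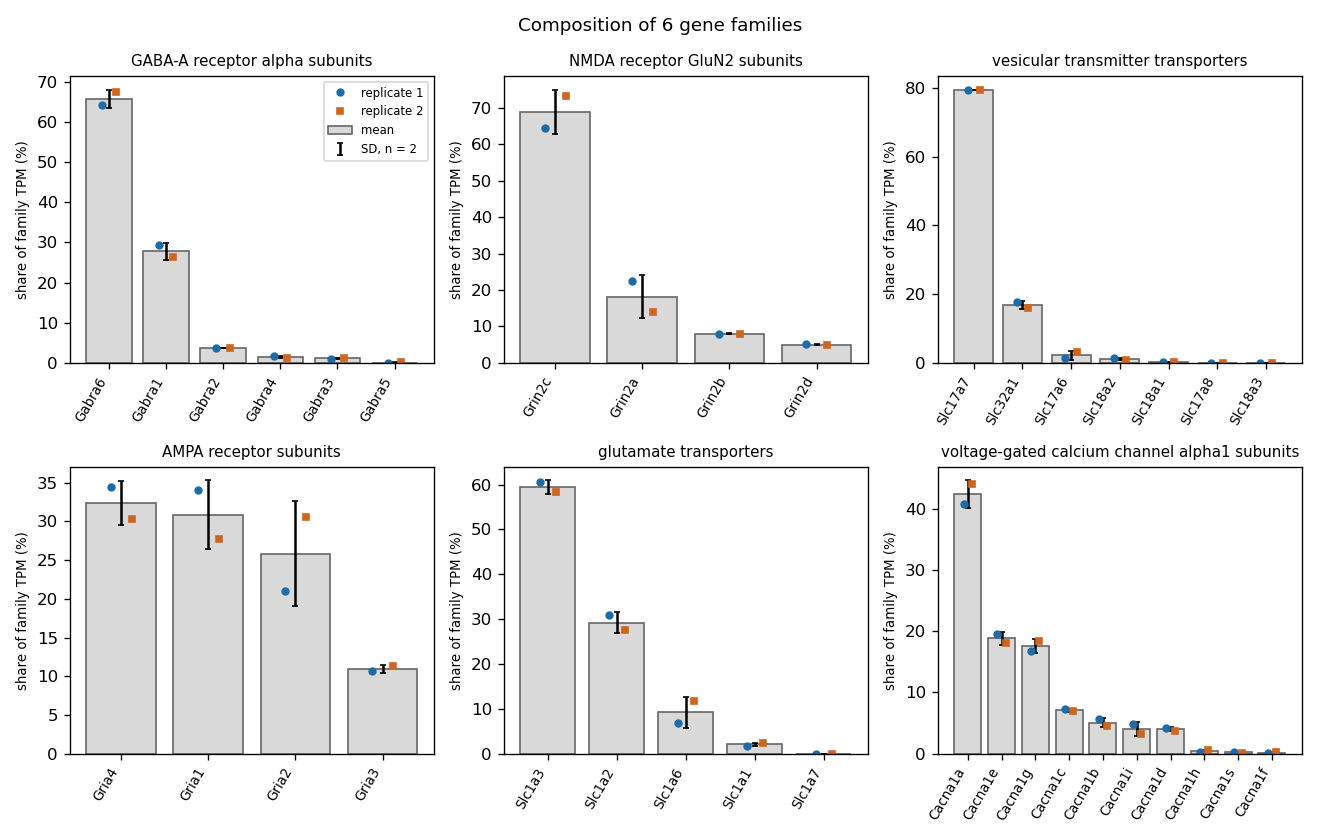
Share of family TPM in percent for the members of 6 gene families; bars are means, error bars the SD of 2 mice, and points the mice. Gabra6 holds 65.8%, Grin2c 68.8% and Slc17a7 79.4% of their families, and the AMPA receptor members exchange rank between the mice.

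Transcript shares were less settled than gene levels. Among 7576 genes with several annotated transcripts, the largest transcript was the same in both mice in 6057 (79.9%, exact 95% interval 79.0% to 80.8%), and its median share was 50.8%. That interval treats genes as independent and holds neither the spread between mice nor the choice of threshold or unit. In the 1519 other genes the leading transcripts of the mice lay a median of 7.17 percentage points apart by their shares in replicate 1. In genes with the same leader, it lay a median of 21.5 points above the next transcript in that replicate. Among 29 neuronal and glial genes fixed for this purpose, 26 had the same leading transcript. Calb1-201 held 91.1% ± 1.28 of Calb1, Cbln1-202 72.4% ± 1.06 of Cbln1, Ntrk2-202 63.0% ± 4.33 of Ntrk2, Gabrg2-202 59.8% ± 0.482 of Gabrg2 and Mapt-204 55.2% ± 0.233 of Mapt. For Gria2 the largest share, 27.4% ± 1.85, was assigned to a retained-intron model, Gria2-208, ahead of the coding Gria2-202 with 21.9% ± 0.0983. In Atp2b2 the leader differed, as Atp2b2-203 had 26.4% in replicate 1 and 43.8% in replicate 2. Pcp2, Calm2, Ptgds and Psap, all highly expressed, also changed leader between the mice, by shares such as 54.9% and 47.5% for Psap-205. Among the 6057 genes with the same leader, it was a retained-intron, processed-transcript or nonsense-mediated decay model in 977 coding genes. With shares computed from counts the leader was the same in 87.1%.

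Gene levels in the mice were close. Across 26774 genes with signal in either mouse, Pearson's r of log2(TPM + 1) was 0.974 and Spearman's rho 0.915, genes not being independent replicates. Across 12913 protein-coding genes r was 0.983. The biological coefficient of variation was 11.4% over 15613 genes, and 18.7%, 12.1% and 9.13% in the lower, middle and upper part of the expression range. Of 12258 genes with a mean count of at least 50, 95.6% lay within 1.5-fold, and the median absolute log2 ratio was 0.16.

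Choroid plexus genes were much higher in replicate 1, and Nrgn, Meis2 and Sst were among the genes higher in replicate 2. By at least 2-fold, 43 genes were higher in replicate 2 and 58 in replicate 1. Ttr (ENSMUSG00000061808), the transthyretin gene of the choroid plexus (chromosome 18, 20665280 to 20674321), had 606 TPM in replicate 1 and 66.0 TPM in replicate 2, a log2 ratio of -3.47 (95% interval -3.58 to -3.36). Kl, the klotho gene, had a log2 ratio of -3.49 (-4.11 to -2.97), Prlr, the prolactin receptor gene, -3.20 (-4.09 to -2.48), F5 -3.14, 1500015O10Rik -2.34, Enpp2, the autotaxin gene, -1.91 (-1.99 to -1.84), Car12 -1.88, Kcnj13 -1.74, Slc4a5 -1.64 and Clic6 -1.12. Nrgn (ENSMUSG00000053310), a calmodulin-binding postsynaptic protein gene (chromosome 9, 37544492 to 37552904), had 3.46 TPM in replicate 1 and 39.0 TPM in replicate 2, a log2 ratio of 3.26 (2.81 to 3.78). Meis2 had a log2 ratio of 2.36 (1.78 to 3.04), Sst, the somatostatin gene, 2.02 (1.40 to 2.74), Kcnc2 1.77, Rasgrf2 1.76, Cpne6 1.74, Miat 1.60, Tcf7l2 1.58 (1.33 to 1.85) and the vesicular glutamate transporter gene Slc17a6 1.49 (1.19 to 1.81). Each ratio compares 1 library with another, so its interval holds counting error only.

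Of the genes higher in replicate 2, 30 of 43 were protein-coding, and of those higher in replicate 1, 30 of 58, against 11347 of all 12258 tested genes. Pseudogenes and small RNAs were among the other differing genes. Gm14288, Gm26244 and Gm5884 had 224, 160 and 129 counts in replicate 2 and 0 in replicate 1, and Gm15772 and Gm6768 had 215 and 124 counts in replicate 1 and 0 in replicate 2, all with ambiguous reads. Of the differing genes 34.9% of those higher in replicate 2 and 50% of those higher in replicate 1 had a posterior standard deviation of at least 5% of the count, against 5.33% of the genes within 2-fold. Without such ambiguous genes, a restriction added after the data were seen, 28 genes were higher in replicate 2 and 29 in replicate 1. Scaling by total counts gave 61 higher in replicate 2 and 38 higher in replicate 1, as it moved the median gene by 0.11 on the log2 scale; deposited TPM, which moved it by 0.26, gave 181 and 31.

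Of 50 lists with enough counts, 21 lay outside the range of random lists, 11 higher in replicate 2 and 10 higher in replicate 1, where 2.5 would fall outside by chance if genes were independent. The choroid plexus list had a median log2 ratio of -2.36, below all 10000 random medians (central 95% -0.22 to 0.26), with 9 of 10 members higher in replicate 1; Otx2, which other cells also express, was the exception at 0.15. Ependymal genes had a median of -0.82 (4 of 4 higher in replicate 1) and red blood cell genes of -0.77 (5 of 5), with Hba-a1 at -0.96 and Hbb-bs at -0.90. Astrocytes (-0.23, 7 of 10) and mitochondrially encoded genes (-0.28, 15 of 15) lay on the same side. So did Bergmann glia (-0.25, 10 of 10), microglia (-0.28, 8 of 10), molecular layer interneurons (-0.17, 8 of 12), oligodendrocytes (-0.13, 9 of 12) and the AMPA receptor family (-0.20, 3 of 4), though in deposited TPM, where the median of all tested genes was 0.28, the medians of these 5 lists lay above 0. On that scale Bergmann glia and molecular layer interneurons still lay below the central 95% of random lists, at percentiles 0.03 and 1.14, and the other 3 lists lay inside it.

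Higher in replicate 2 were cerebellar nuclei (0.38, 6 of 7 members), Golgi cells (0.38, 3 of 5), heat shock genes (0.37, 10 of 12), voltage-gated calcium channels (0.34, 8 of 8), glucocorticoid responsive genes (0.32, 12 of 12), Kv3 channels (0.32, 4 of 4), meningeal fibroblasts (0.28, 6 of 9), zebrin-positive Purkinje genes (0.26, 4 of 5), immediate early genes (0.22, 13 of 17), endothelial cells (0.20, 8 of 10) and granule cells (0.18, 11 of 14). The glucocorticoid list included the cell cycle inhibitor gene Cdkn1a at 0.85, the kinase gene Sgk1 at 0.32, the clock gene Per1 at 0.26 and Tsc22d3 at 0.07. Within the nuclear list, Lhx9 had 7 counts in replicate 1 and 87 in replicate 2, a log2 ratio of 3.34 (2.33 to 4.79), Slc17a6 one of 1.49 and Nefl one of -0.07. Slc6a5, the glycine transporter gene, belongs to both the nuclear and the Golgi cell list and is the median of each. The telencephalic list had a median of 0.01, the Purkinje cell list of -0.06, unipolar brush cells of 0.20, oligodendrocyte precursors of -0.01, mural cells of 0.05, circadian genes of -0.06, ataxia genes of 0.00 and imprinted genes of 0.04, all inside the random range. The call ended under at least 1 alternative for 10 of the 21 lists: Golgi cells, oligodendrocytes, microglia, endothelial cells, meningeal fibroblasts, immediate early genes, mitochondrially encoded genes, zebrin-positive genes, AMPA receptors and Kv3 channels. The call for ependymal cells held under the alternatives that gave it a value but ended when 1 member was left out.

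**Figure D3:**
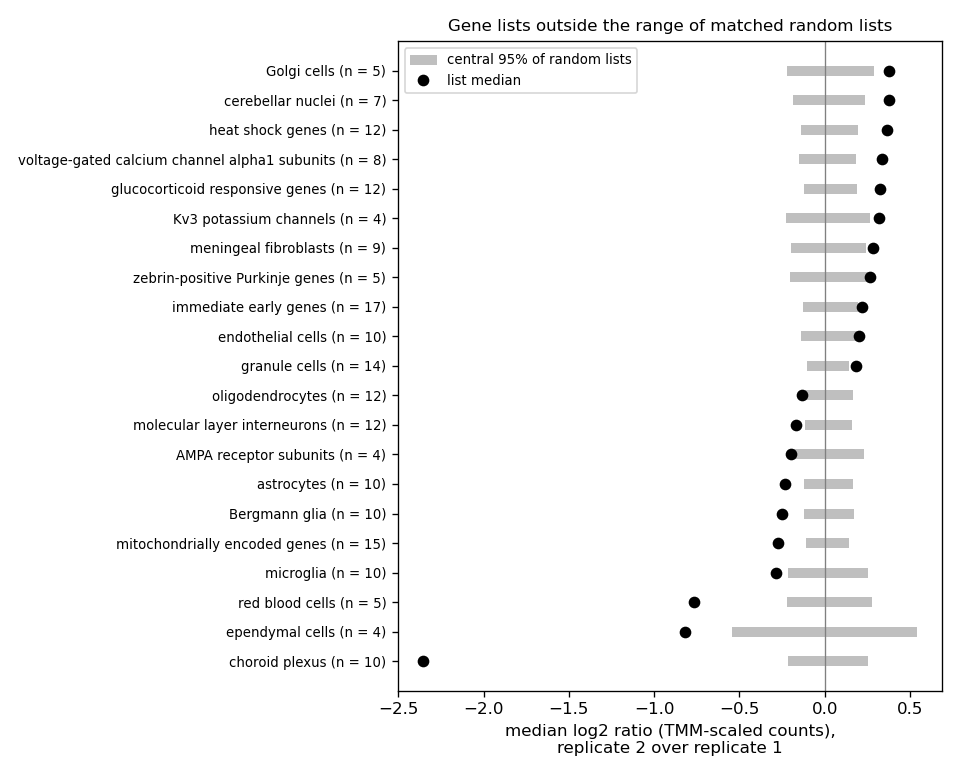
Median log2 ratio of replicate 2 over replicate 1 (horizontal axis, TMM-scaled counts) for the 21 lists outside the range of matched random lists; points are list medians and grey bars the central 95% of 10000 random lists. The choroid plexus list lies at -2.36, apart from all others; in deposited TPM, which moves the median gene by 0.26, the Bergmann glia, interneuron, oligodendrocyte, microglia and AMPA receptor medians lie above 0.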

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

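The tests on pooled telencephalic genes, on the midbrain genes not detected in both mice and on endothelial cells were chosen only after the result was seen.

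The summed ERCC and tRNA rows, which lie outside the gene measurements, held more counts than the 3 that a count of 0 allows, and the phiX row held 0 in both mice. ERCC spike-in rows had 22 counts in replicate 1, in 7 of 96 rows, and 11 in replicate 2, in 5 of 96 rows, and the labels list a spike-in reference. tRNA rows had 4164 counts in replicate 1 and 4387 in replicate 2, or 0.0318% and 0.0314% of the counts.

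Choroid plexus genes were higher in replicate 1, with a median log2 ratio of -2.36 over 10 genes. Removing a linear trend with GC content and gene length left the median at -2.30 (bootstrap 95% interval over genes -3.39 to -1.41). The fitted trend was only 0.13 on the log2 scale per 10% of GC content and 0.038 per doubling of length. So shallow a trend could not account for the difference. Its removal says nothing on other effects of GC content or length. A candidate explanation is more choroid plexus tissue in the replicate 1 sample: of 13 further choroid plexus genes not in the fixed list, the 8 with enough counts had a median of -1.77 (bootstrap interval -3.36 to -0.75), with Sostdc1 at -4.27, Tmem72 at -4.05 and Cldn2 at -2.10, and, among the 3 of the 13 detected in both mice, Lbp at -1.44, Sulf1 at -0.58 and Rdh5 at -0.46. The median of the 8 genes met the bound fixed beforehand for this explanation. Both bootstrap intervals resample genes, which vary together within 1 cell type, and not mice. They do not measure the spread between mice. The design names no group, so no cause of such a difference in tissue between the mice was tested.

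Nrgn, Meis2, Sst, Tcf7l2 and Slc17a6 were higher in replicate 2. Their median was 2.02 before and 2.02 after removal of the linear trend with GC content and length. These genes had already passed the 2-fold rule, and the fitted trend was shallow, at 0.13 per 10% of GC content and 0.038 per doubling of length. Its removal could therefore hardly move their median, and it decides nothing beyond that linear trend. Slc17a6 also belongs to the cerebellar nuclei list and Sst to the Golgi cell list, which each had a median log2 ratio of 0.38. A source within the cerebellum was not tested. Midbrain tissue beside the cerebellum stays open. The test fixed beforehand, on 14 further midbrain genes, gave a pooled log2 ratio of 0.0488 (-0.0994 to 0.198), below its bound of 0.5 and so against this source; that bound was badly chosen, because genes detected in both mice, Cck (415 and 405 counts), Ebf3 and Lef1, gave 86.5% of the pooled counts and would hide a small admixture. The 11 genes not detected in both mice, a restriction made after their counts were seen and so no independent evidence, had 50 and 152 counts and a ratio of 1.39 (0.93 to 1.89), with Tac1 at 2 and 35 counts and, the other way, Nts at 9 and 4 and Pax7 at 1 and 0. Telencephalic tissue cannot be told apart from no such tissue, because 11 patterning genes had only 16.6 and 28 counts in all and a ratio of 0.54 (-0.40 to 1.48). The tests on midbrain and telencephalic tissue thus decided neither source, and no other biological explanation was tested.

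Glucocorticoid responsive genes were higher in replicate 2 in 12 of 12 cases. After the trend with GC content and length was removed their median, 0.28, stood at percentile 99.96 of random lists, which argues against that trend. More endothelial cells in replicate 2 cannot be told apart from other sources. The endothelial minus the glucocorticoid median was -0.12, with a bootstrap interval over genes from -0.38 to 0.06 that holds 0. A difference in the state or handling of the animals was not tested.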

How the results depend on the processing

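The alternative on genes with unambiguous reads was chosen after the data were seen, and the others beforehand. Of 159 comparisons of a main result with an alternative, 125 stayed the same, and among 782 for single lists and families 690 did. List levels, family shares and the median share of the largest transcript were judged by the spread between the mice. Counts were judged by a 1.5-fold limit and list shifts by the side of the random range. Agreement of leading transcripts was judged by its exact interval over genes and Pearson's r by a bootstrap SD over genes. The coefficient of variation was judged by the error of its recovery on simulated counts. The last 3 limits hold no spread between the mice. For list levels and family shares, leaving out 1 mouse never moves a mean by more than the SD. The scale cancels in FPKM for list ratios and family shares, and in protein-coding TPM for list ratios, so these could move only by rounding. Such comparisons are among the 125 and the 690 and say nothing on stability. The cause of each move was not tested, except where the setting itself sets it. Detected genes ranged from 10532 to 20791, and those without replicate 1 or without replicate 2 were 16774 and 16202. Without division by length (TMM-scaled counts), 11 of the 25 highest genes were shared, and the granule cell list exceeded Purkinje cells by 0.74 and oligodendrocytes by 1.69 on the log2 scale. The mean of log2(TPM + 1) gave 0.67 over oligodendrocytes. Over the telencephalic list, 10.38 in the main result, posterior mean TPM gave 8.28, detected members only 1.92, the mean of log2(TPM + 1) 6.14 and a pseudocount of 0.1 gave 9.63. By expected count the shares were 49.0% for Gabra6, 60.2% for Grin2c and 79.1% for Slc17a7, which had 79.1% by posterior mean TPM. The same leading transcript was found in 76.7% of genes at 1 TPM, 83.3% at 20 TPM and 87.1% by expected count. Pearson's r was 0.923 and 0.989 with pseudocounts of 0.1 and 10, 0.979 in FPKM and 0.993 in TMM-scaled counts. The coefficient of variation was 12.6% with 1 count in either mouse and 10.3% with 100 counts in both. Genes higher in replicate 2 and in replicate 1 numbered 181 and 31 in deposited TPM, 301 and 236 at 1.5-fold, 6 and 11 at 4-fold, 569 and 735 at a mean count of 5, 1 and 6 at a mean count of 500, and 28 and 29 with unambiguous reads; total count scaling gave 38 higher in replicate 1, and 81 of its 99 differing genes were among the 101 of the main result. In deposited TPM, where the median gene moved by 0.26, list medians turned positive for molecular layer interneurons (0.10), Bergmann glia (0.00883), oligodendrocytes (0.14), microglia (0.12) and AMPA receptors (0.0504). Of the 21 lists outside the random range 11 kept their side under each of the 10 settings that gave a value. With each member left out as well, 10 of these did. The exception was ependymal cells, at -0.31, which had too few genes for a value at a mean count of 100. Median-of-ratios, total count and upper quartile scaling, and leaving mitochondrially encoded genes out of library sizes, moved every log2 ratio alike. They could not change a percentile, so only the other settings tested these calls. The 4 lists with entries of their own, choroid plexus, glucocorticoid responsive genes, cerebellar nuclei and red blood cells, were picked after the results were seen. Comparisons between the mice need both, so none could be repeated with a mouse left out. No paired analysis was possible because there is only 1 group. Depth limits genes near the 3 counts that a count of 0 allows.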

Other observations

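The genes used in this part were named in fixed lists, and no test was added after the values were seen.

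GABA-A receptor subunits other than alpha were shared between Gabrg2 with 27.7% ± 1.39 of their TPM, Gabrb2 with 26.1% ± 2.56, Gabrb3 with 21.3% ± 0.362 and Gabrd, a subunit of extrasynaptic receptors, with 20.3% ± 3.68. Among kainate and delta receptors, Grid2, the delta receptor of Purkinje cells, held 39.9% ± 2.89 and Grik2 28.6% ± 0.269. Camk2b exceeded Camk2a by 2.60 ± 0.01 on the log2 scale. All 12 listed synaptotagmins were detected, led by Syt11 at 203 ± 18.5 TPM, Syt1 at 179 ± 19.6 TPM and Syt2 at 153 ± 27.5 TPM. The 4 FGF homologous factors were detected, Fgf12 with 39.0% ± 2.61, Fgf14 with 23.7% ± 0.172, Fgf11 with 21.6% ± 1.93 and Fgf13 with 15.7% ± 0.498 of their TPM.

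Among heat shock genes Hspa8, Hsp90aa1 and Hsp90ab1 stood at 1088 ± 281, 783 ± 143 and 706 ± 155 TPM, and Hspa1b stood at 1.42 ± 0.785 TPM. Among immediate early genes Dusp1 stood at 27.3 ± 2.81 TPM, Jun at 17.8 ± 0.962 TPM, Fos at 17.2 ± 6.06 TPM and Nr4a2 at 14.7 ± 8.84 TPM, and Fosb, Egr2, Egr3 and Egr4 were under 1 TPM in at least 1 mouse.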
